A study of Arabidopsis thaliana with 18 samples.

How the data were processed

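Transcripts of whole Arabidopsis seedlings were measured on 18 Affymetrix ATH1 arrays, in 8 groups of genotype and light. The dark groups of wild type and jmj17-1 held 3 arrays each and the 6 groups after 2, 4 or 8 h of light held 2 each. Samples were grouped by genotype, hours of light and replicate number as their titles give them.

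Arrays were scanned with GCOS 1.4, per the submitters' processing notes. Per the file headers, the authors summarized probes by RMA with quantile normalization and kept a list by a moderated t-test at p of at most 0.05 and a fold of at least 1.0, without stating the comparison. The deposited table gives intensity on the linear scale for 6847 of the array's 22810 probe sets, from 3.22 to 10892.5. It heads these columns as raw data, but their log2 values, centred on each probe set's median over the arrays, equal its own normalized block, so they are RMA values. That normalized block and the authors' fold change are in log2, and the 18 normalized columns were used only for this check. The authors' fold change, positive for 3818 probe sets and negative for 3029, equals the difference of the dark group means. A second deposited file holds centred log2 values for all 22810 probe sets. Its columns equal the column of their own title in the first table for 2 arrays and that of another title for 16. The first table, whose columns carry the titles, was therefore used throughout. The second served only as an alternative, with each column taken as the array whose values it equals. When the second file was taken by its own labels, 0 probe sets passed in each genotype comparison and each wild-type light comparison (limma), 4057 in the mutant at 2 h and 443 in the mutant at 4 h. RNA extraction amounts, harvest order and the origin of the replicates are not given in the sources used here.

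Because of that list, 15963 probe sets were left out. Every probe set kept has an unadjusted p of at most 0.0237 (limma on the arrays compared) in jmj17-1 at 2 h of light against dark, while 9.8 percent of the others fall under 0.05 there. Between genotypes the probe sets kept also fell under 0.05 more often than the others. The shares were 15.9 against 7.3 percent in the dark, 20.3 against 10.6 at 2 h, 17.4 against 8.4 at 4 h and 16.4 against 9.2 at 8 h. The mutant dark and 2 h arrays, between which every probe set kept differed, also enter the fit behind the genotype comparisons and interactions. The adjusted p-values of those comparisons are thus not independent of how the list was selected, and how far this moved them was not tested. Median intensity per array ran from 144 to 161, and the lowest intensity was 3.22; the array background is not given in the sources used here. For named genes the percent of probe sets with a dimmer group mean was computed. Of the 6847 probe sets, 6514 name 1 locus, 285 several and 48 none. Only those of 1 locus were named or used in lists. Gene names came from the deposited table and the TAIR10.1 assembly of RefSeq. The deposited table does not name the genome build of its own coordinates, and none are printed here.

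Log2 intensities of all 18 arrays were fitted together with 1 mean per group, in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes). Residual degrees of freedom were 10, prior degrees of freedom 4.91 and the prior SD 0.114 on the log2 scale. There were 14 comparisons. They were jmj17-1 against wild type at each time and averaged over the 4 times with equal weights, each light time against dark in each genotype, and the genotype by light interaction at each light time. A probe set passed at an adjusted p under 0.05 (Benjamini-Hochberg over the 6847 probe sets of a comparison). The fit pooled its spread over all groups since the light groups hold 2 arrays. No batch term was used because the labels give no batch. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

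The comparisons, thresholds, alternatives and 22 gene lists were fixed before the data were examined. The lists held 378 loci, of which 221 had a probe set of 1 locus: chlorophyll biosynthesis, heme and tetrapyrrole control, light-harvesting antenna, photosystems and electron transport, Calvin-Benson cycle, photoreceptors and light signalling, early light-induced proteins, carotenoids, flavonoids and anthocyanins, dark growth and shade, dark and sugar starvation, circadian clock, abscisic acid and dehydration, singlet oxygen and oxidative stress, heat shock, plastid gene expression and import, histone lysine methylation, fatty acid breakdown and glyoxylate cycle, seed storage and embryo, root, dividing cells, and pathogen defence. Each gene was represented by its brightest probe set. Lists with at least 3 measured members were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Seed storage, with 1 measured gene, and pathogen defence, with 0, were not tested.

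Named genes followed a fixed rule. They were the 6 largest rises and 6 largest falls of each genotype comparison and interaction that passed (5 and 5 for light), and up to 4 members of each list with the smallest p. For the comparisons of 2 groups the arrays of both also had to be apart. JMJ17, HEMA1, CHLH, CHLD, GUN4, CHL27, CAO, PORA, PORB, PORC, HY5, PIF1, PIF3, GLK1 and GLK2 were always included where measured. JMJ17, CHLD, PIF1 and GLK1 had no probe set of 1 locus in the table and are not analysed here.

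The fit was tested on simulated data with 200 of 6847 probe sets changed. In the dark comparison 74 percent of changes of 0.5 log2 were recovered, 98 percent of changes of 1 and 100 percent of changes of 2, with 5 false calls among 190. For the light times 54 to 60 percent were recovered at 0.5 and 94 to 96 percent at 1, with 11 to 13 false calls. For the average 96 percent were recovered at 0.5. A list shifted on purpose passed (camera adjusted p = 2.55e-45) and 0 of 21 others did. The simulated noise was drawn independently for each probe set, so this check does not cover lists whose genes move together. It also had the same spread in every array. In the data the array weights of limma, low for arrays of wide spread, ran from 0.215 for mutant dark replicate 2 to 2.576 for the mutant arrays at 4 h. The shares recovered and the false calls thus do not cover arrays of unequal spread.

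Alternatives were quantile normalization and median centring of the arrays, leaving out the dimmest 40 percent of probe sets, adding 16 before the log, eBayes with trend and robust settings, array weights, the replicate number as a block, fits of only the groups compared, a fold of at least 1.5 beside the adjusted p, and leaving out each array in turn. For lists they were an estimated correlation, all probe sets of a gene, the block and quantile normalization. Added after seeing the data were the full value table with columns matched by value, adjustment over 22810 probe sets, lists set against the full table, and an enrichment test of gene ontology terms.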

Results

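Transcript levels were measured on ATH1 arrays in whole seedlings of wild-type Col-0 and the mutant jmj17-1, grown without sugar. Seedlings came straight from 4 days of dark or had 2, 4 or 8 h of light after it. Each dark group held 3 arrays and each light group 2, and their number limits the precision. Values are log2 RMA intensities of the 6847 probe sets in the deposited table, and changes are stated relative to the deposited normalization. JMJ17 itself, a histone H3K4 demethylase gene, had no 1-gene probe set in that table and is not analysed here. Where a group mean was among the dimmest 5 percent of probe sets, the exact size of a difference that uses it is not established. Between genotypes and in the interactions this held for AT1G50410 in the mutant, EARLI1 in the mutant at all times but 2 h and in the wild type in the dark, OM66 in the mutant in the dark and in both genotypes at 8 h, CYP81D8 in the mutant in the dark, CYP81F2 in the mutant at 4 h, HSFA2 and HSP21 in both dark groups, and ACA2 in these and in the mutant at 2 h. Light responses were not checked for it. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

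In the dark, the mutant had less transcript of AT4G36430, which encodes a class III peroxidase: -2.21 ± 0.18 (log2 difference ± SE, n = 3 and 3; adjusted p = 8.13e-06). Its level was 7.68 ± 0.17 in jmj17-1 and 9.89 ± 0.16 in wild type (mean ± SD). AT1G50410, which encodes an SNF2-type chromatin remodelling factor, fell by 1.87 ± 0.12 (adjusted p = 7.25e-07), and the defence gene ECS1 fell by 1.69 ± 0.19 (adjusted p = 0.000209). OLEO2, for an oil body protein of seeds, fell by 1.76 ± 0.37, with a spread of 0.71 between the 3 mutant arrays and an adjusted p of 0.0317. The largest rise was AT5G26270, for a membrane protein of unknown role, at 0.76 ± 0.08 (adjusted p = 0.000143). LUT2, a cyclase gene of lutein synthesis, rose by 0.57 ± 0.13 (adjusted p = 0.0437), and JMJ13, another JmjC demethylase gene, by 0.42 ± 0.09 (adjusted p = 0.0273). The clock gene GI fell by 0.40 ± 0.09 (adjusted p = 0.042). Without mutant replicate 2, LUT2, OLEO2, JMJ13 and GI no longer passed.

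In all, 42 probe sets rose and 81 fell in the dark, 123 of 6847 (limma, adjusted p under 0.05, Benjamini-Hochberg). Their median size was 0.52 and 12 differed at least 2-fold. Of the calls, 65.9 percent were falls, against 75.6 percent after quantile normalization and 81.1 percent after median centring. The count was 24, 44 and 47 without wild-type replicates 3, 1 and 2, and 445, 49 and 264 without mutant replicates 1, 2 and 3. The excess of falls turned without mutant replicate 1 (247 up, 198 down) and without mutant replicate 3 (148 up, 116 down). The count was 41 without the dimmest 40 percent of probe sets, 79 with array weights and 13 with the 6 dark arrays alone.

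**Figure D1:**
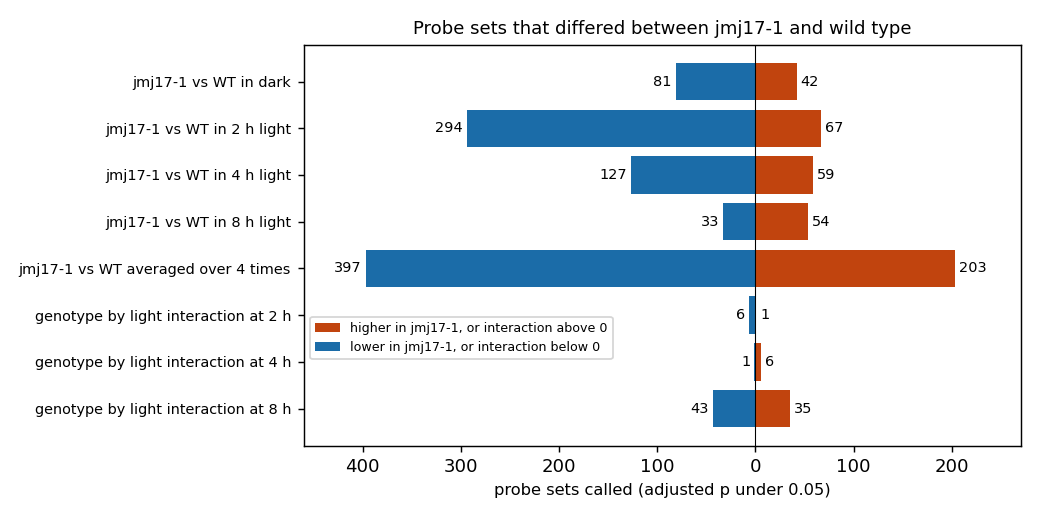
Bars count the probe sets, of 6847, that were higher (right) or lower (left) in jmj17-1 than in wild type at each time and on average, and those with a genotype by light interaction above or below 0. The 2 h light bar reaches 294 lower and 67 higher, while 8 h light has 33 lower and 54 higher.

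None of the 16 measured chlorophyll biosynthesis genes passed singly in the dark, adjusted over all probe sets or over the list alone. All 16 were higher in the mutant, with a median of 0.36, among them PORC (0.71 ± 0.37, adjusted p = 0.282), GUN4 (0.62 ± 0.28, adjusted p = 0.204) and HEMA1 (0.28 ± 0.12, adjusted p = 0.189). As a list they were higher (camera adjusted p = 0.00308, adjusted p = 0.638 with an estimated correlation). Mutant replicate 2 stood apart, with a correlation of 0.985 to the other mutant dark arrays against 0.995 between those, and without it the list median was 0.01, with PORC at 0.02, GUN4 at 0.13 and HEMA1 at 0.09. The 26 photosystem genes had a median of 0.27 (camera adjusted p = 0.000377, adjusted p = 0.638 with an estimated correlation), and 0.06 without that array. PSAG, for a photosystem I subunit, stood at 0.40 ± 0.15 (adjusted p = 0.155) and PETE2, for plastocyanin, at 0.44 ± 0.18 (adjusted p = 0.176), and at 0.15 and 0.13 without that array. For 13 Calvin-Benson genes the median was 0.23, and 0.00 without that array (camera adjusted p = 0.0311, adjusted p = 0.639 with an estimated correlation). Antenna genes had a median of 0.16, and -0.09 without that array, and did not pass (camera adjusted p = 0.187), with LHCA6 at 0.65 ± 0.27 (adjusted p = 0.187), or 0.17 without that array. Without that array the chlorophyll, photosystem and Calvin-Benson calls were lost.

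Of 12 carotenoid genes only LUT2 passed in the dark, and 2 passed when adjusted over the list alone, the other being PSY at 0.49 ± 0.17, or 0.20 without mutant replicate 2. The list was higher (median 0.18, and 0.05 without mutant replicate 2; camera adjusted p = 0.0311, adjusted p = 0.638 with an estimated correlation), a call lost without mutant replicate 1, mutant replicate 2 or wild-type replicate 2. Of 22 photoreceptor and light signalling genes 0 passed, and 5 were higher when adjusted over the list alone, among them HYH (0.99 ± 0.32, or 0.46 without mutant replicate 2) and FHL (0.36 ± 0.09). That list was higher too (median 0.12; camera adjusted p = 0.0311, adjusted p = 0.566 with an estimated correlation), with a median of 0.10 without mutant replicate 2, and its call was lost without mutant replicate 1.

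**Figure D2:**
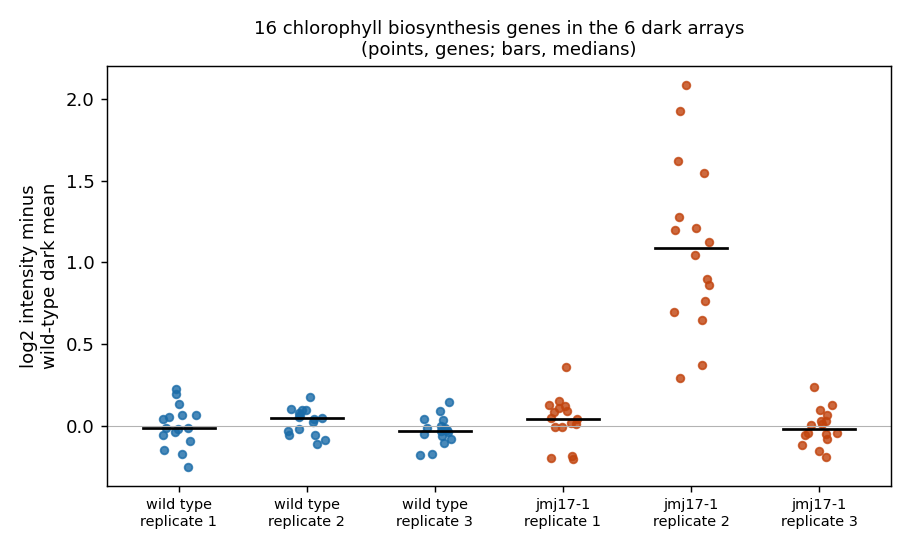
Log2 difference of each of 16 chlorophyll biosynthesis genes from the wild-type dark mean, in the 3 wild-type and 3 mutant dark arrays, with array medians. Mutant replicate 2 stands apart from the other arrays, and without it the median difference between the genotypes is 0.01.

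Of 11 singlet oxygen and oxidative stress genes, OM66, for a protein of the outer mitochondrial membrane, fell in the dark by 0.99 ± 0.16 (adjusted p = 0.00844), and 6 were lower when adjusted over the list alone. The list was lower (median -0.27; camera adjusted p = 0.000228, adjusted p = 0.398 with an estimated correlation), with a median of -0.18 without mutant replicate 2.

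After 2 h of light, the mutant had less transcript of several stress genes. OM66 fell by 1.57 ± 0.20 against wild type (n = 2 and 2; adjusted p = 0.000483). WRKY40, a transcription factor gene, fell by 0.99 ± 0.12 (adjusted p = 0.000396), and ERF6, a gene for an ethylene response factor, by 1.08 ± 0.16 (adjusted p = 0.00149). HSFA2, for a heat stress transcription factor, fell by 1.05 ± 0.23 (adjusted p = 0.0161), and HSP101, a chaperone gene, by 0.89 ± 0.19 (adjusted p = 0.0122). CYP81F2, of indole glucosinolate modification, fell by 1.66 ± 0.32 (adjusted p = 0.00779). Among the largest rises were 2 genes of gibberellin synthesis, GA20OX1 at 1.04 ± 0.21 (adjusted p = 0.0101) and GA3OX1 at 0.90 ± 0.16 (adjusted p = 0.00402), with the auxin-responsive SAUR28 at 0.90 ± 0.16 (adjusted p = 0.00481).

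Of the 11 singlet oxygen genes, 6 fell at 2 h and 0 rose, or 8 fell when adjusted over the list alone, SIB1 among them (-1.15 ± 0.24, adjusted p = 0.0131). The list median was -0.64 (camera adjusted p = 1.10e-06, adjusted p = 0.131 with an estimated correlation). Of 8 heat shock genes 3 fell, or 7 over the list alone, and all were lower (median -0.75; camera adjusted p = 2.08e-05, adjusted p = 0.67 with an estimated correlation). The heat shock falls numbered 0 without wild-type replicate 1, mutant replicate 1 or mutant replicate 2 and 7 without wild-type replicate 2, and 6 without mutant dark replicate 2, with a median of -0.40 without wild-type replicate 1 and -1.10 without wild-type replicate 2. The singlet oxygen falls numbered 3 without wild-type replicate 1, mutant replicate 1 or mutant replicate 2. Of 18 starvation genes 4 fell, or 6 over the list alone: SEN1 (-0.51 ± 0.10), ASN1 (-0.46 ± 0.11), MCCA (-0.42 ± 0.09) and MCCB (-0.39 ± 0.10), and the list as a whole did not pass (camera adjusted p = 0.05004).

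Of 13 antenna genes LHCB4.3 rose, by 0.50 ± 0.13 (adjusted p = 0.0372), and the list was higher (median 0.14; camera adjusted p = 0.032, adjusted p = 0.865 with an estimated correlation). Photosystem genes (median 0.17; camera adjusted p = 0.00105) and Calvin-Benson genes (median 0.21; camera adjusted p = 0.0195) were also higher as lists, each with an adjusted p = 0.865 with an estimated correlation. The antenna and Calvin-Benson calls were lost after quantile normalization and without either wild-type array, and the antenna call also without mutant replicate 1. None of the 16 chlorophyll genes passed with all arrays (median 0.11; camera adjusted p = 0.0934), and CHLH was at 0.06, HEMA1 at 0.12 and PORA at -0.51 ± 0.33 (adjusted p = 0.417). Without mutant dark replicate 2, which widens the pooled spread, PORA passed at 2 h (-0.51, adjusted p = 0.035).

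At 2 h, 67 probe sets rose and 294 fell, 361 in all (limma, adjusted p under 0.05). Falls made up 81.4 percent of the calls, against 64.0 percent after quantile normalization and 65.1 percent after median centring. The count was 140 without wild-type replicate 1, and 130 and 88 without mutant replicates 1 and 2. It was 186 without the dimmest 40 percent of probe sets and 227 with the 4 arrays alone.

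After 4 h of light, chaperone genes were still lower in the mutant: Hsp70b by -1.50 ± 0.20 (n = 2 and 2; adjusted p = 0.00209), HSP23.6 by -1.18 ± 0.22 (adjusted p = 0.0131), HSP101 by -1.09 ± 0.19 (adjusted p = 0.00658) and HSP17.6II by -1.15 ± 0.23 (adjusted p = 0.0172). ERF6 fell by 1.05 ± 0.16 (adjusted p = 0.00402), WRKY40 by 0.90 ± 0.12 (adjusted p = 0.00239) and WRKY33, a gene of defence signalling, by 1.04 ± 0.22 (adjusted p = 0.0191). CYP81F2 fell by 1.96 ± 0.32 (adjusted p = 0.00525), while CYP81F4, of the same family and pathway, rose by 1.22 ± 0.22 (adjusted p = 0.00927). ICS2, for an isochorismate synthase, rose by 1.21 ± 0.14 (adjusted p = 0.000581).

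Heat shock genes fell in 6 of 8 cases at 4 h, and in 8 of 8 when adjusted over the list alone (median -1.08; camera adjusted p = 2.63e-10, adjusted p = 0.15 with an estimated correlation). These falls numbered 0 without wild-type replicate 1 or mutant replicate 2 and 3 without mutant replicate 1. Singlet oxygen genes fell in 6 of 11, or 7 over the list alone (median -0.66; camera adjusted p = 3.92e-06, adjusted p = 0.15 with an estimated correlation), and in 2, 2 and 1 without wild-type replicate 1, mutant replicate 1 and mutant replicate 2. All 10 flavonoid and anthocyanin genes were higher, 0 singly and 5 when adjusted over the list alone (median 0.47; camera adjusted p = 5.38e-06, adjusted p = 0.245 with an estimated correlation). CHIL, of flavonoid synthesis, stood at 0.81 ± 0.26 (adjusted p = 0.129) and PAL1, for the first enzyme of the phenylpropanoid pathway, at 0.38 ± 0.12 (adjusted p = 0.123). Of 18 starvation genes BCAT2, of amino acid breakdown, fell by 0.69 ± 0.13 (adjusted p = 0.0156), and the list was lower (median -0.15; camera adjusted p = 0.000394, adjusted p = 0.627 with an estimated correlation). Without mutant dark replicate 2, DIN2 passed beside BCAT2. Abscisic acid and dehydration genes were higher as a list (median 0.30; camera adjusted p = 0.0157, adjusted p = 0.849 with an estimated correlation), with 0 of 14 past the threshold, and the call was lost after quantile normalization and without replicate 2 of either genotype. Chlorophyll genes did not pass (median 0.13; camera adjusted p = 0.242), but DVR, of the same pathway, passed at 0.59 without mutant dark replicate 2 (adjusted p = 0.0228), and so did 1 flavonoid gene, CHI, at 0.47 (adjusted p = 0.0466), and 1 abscisic acid gene, HAI3, at 0.47 (adjusted p = 0.0242).

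At 4 h, 59 probe sets rose and 127 fell, 186 in all (limma, adjusted p under 0.05). The count was 88 and 114 without wild-type replicates 1 and 2, and 51 and 11 without mutant replicates 1 and 2. It was 86 without the dimmest 40 percent of probe sets, 322 with array weights and 120 with the 4 arrays alone.

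**Figure D3:**
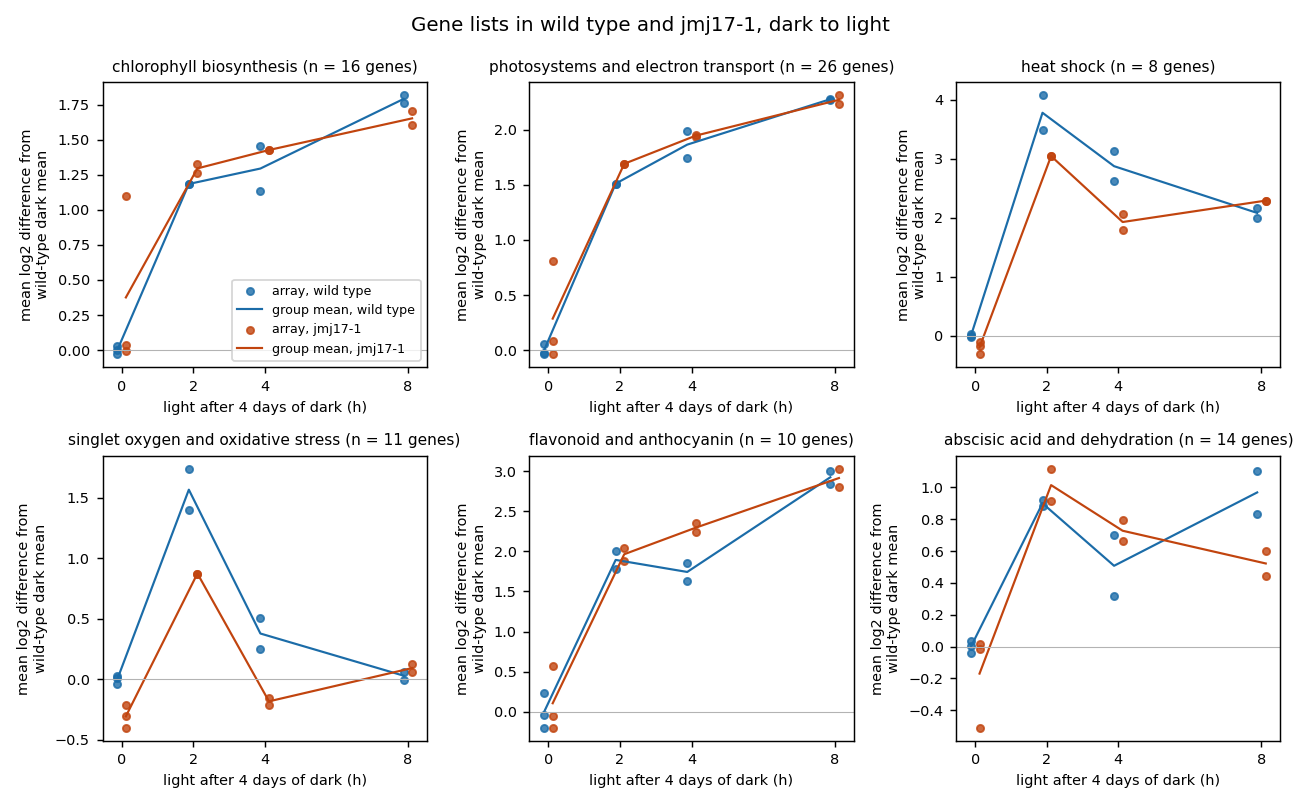
Mean log2 difference of 6 gene lists from the wild-type dark mean (vertical) against hours of light (horizontal), with a point for each array and lines through group means. Heat shock and singlet oxygen lists are lower in jmj17-1 at 2 h (median differences -0.75 and -0.64) and 4 h (-1.08 and -0.66).

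After 8 h of light, PHI-1, a gene of cell expansion, was higher in the mutant by 1.17 ± 0.11 (8.13 ± 0.10 against 6.96 ± 0.01, mean ± SD, n = 2 and 2; adjusted p = 3.47e-05). HSP21, for a chloroplast chaperone, rose by 1.16 ± 0.23 (adjusted p = 0.0208), and XTH15, of cell wall remodelling, by 0.68 ± 0.13 (adjusted p = 0.0192). NAC019, a transcription factor gene of abscisic acid and dehydration responses, fell by 1.26 ± 0.26 (adjusted p = 0.0253), and the expansin gene EXPA10 by 1.09 ± 0.17 (adjusted p = 0.00671).

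All 14 abscisic acid and dehydration genes were lower at 8 h, 0 singly and 6 when adjusted over the list alone (median -0.41; camera adjusted p = 3.08e-06, adjusted p = 0.546 with an estimated correlation). RD29A stood at -0.97 ± 0.28 (adjusted p = 0.102), HAI2 at -0.96 ± 0.30 (adjusted p = 0.142) and ABI1 at -0.48 ± 0.13 (adjusted p = 0.086). Without mutant dark replicate 2, RD29A (adjusted p = 0.0153) and ABI1 (adjusted p = 0.04) passed as lower. Photoreceptor and light signalling genes were lower as a list, with 0 of 22 singly and 2 when adjusted over the list alone (median -0.18; camera adjusted p = 0.00416, adjusted p = 0.546 with an estimated correlation). COP1, for a ubiquitin ligase that represses light responses, stood at -0.33 ± 0.09 (adjusted p = 0.0769). Carotenoid genes were lower too (median -0.19; camera adjusted p = 0.0248, adjusted p = 0.546 with an estimated correlation), a call lost without any 1 of the 4 arrays at 8 h. Chlorophyll genes were lower in 15 of 16 cases without passing (median -0.15; camera adjusted p = 0.304), with GUN4 at -0.17 and PORC at -0.20 ± 0.46. Heat shock genes had a median of 0.16, did not pass as a list (camera adjusted p = 0.175), and 2 were higher when adjusted over the list alone. HSP23.6 stood at 0.74 ± 0.22 (adjusted p = 0.124) and HSP18.2 at 0.70 ± 0.19 (adjusted p = 0.0901). Singlet oxygen genes had a median of 0.05 at 8 h and did not pass as a list.

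At 8 h, 54 probe sets rose and 33 fell, 87 in all (limma, adjusted p under 0.05). The count was 14 and 7 without wild-type replicates 1 and 2 and 10 without mutant replicate 1. The excess of rises was not stable: 112 up and 114 down with array weights (226), 45 and 47 with every probe set of the value table, and 35 and 45 without mutant replicate 2.

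Among probe sets of 1 gene, 3 differed between the genotypes at all 4 times. AT1G50410 fell by 1.87 in the dark, 2.71 at 2 h, 2.69 at 4 h and 2.65 at 8 h of light (averaged -2.48 ± 0.07, adjusted p = 5.34e-12). Its mutant means were 3.89 in the dark and 3.10 at 2 h, where only 4.53 and 1.04 percent of probe sets were dimmer, so its course over time is not established either. AT4G36430 fell by 2.21, 2.41, 1.44 and 1.92 at the same times (averaged -2.00 ± 0.11, adjusted p = 1.64e-08), and AT5G26270 rose by 0.76, 0.96, 1.12 and 1.16 (averaged 1.00 ± 0.05, adjusted p = 6.76e-09). On the average of the 4 times GSTU12, for a glutathione transferase, fell by 1.01 ± 0.10 (adjusted p = 4.78e-05), EARLI1, for a cell wall protein, by 0.98 ± 0.21 (adjusted p = 0.0098) and CYP81D8, a stress-responsive cytochrome P450 gene, by 0.90 ± 0.11 (adjusted p = 0.000288). These genes were not apart at all 4 times. GSTU12 passed in the 8 h interaction at 1.37, so its difference between genotypes was not the same in the dark and at 8 h. EXPB1, an expansin gene, rose by 0.55 ± 0.09 (adjusted p = 0.00262). ACX2, an acyl-CoA oxidase gene of fatty acid breakdown, fell by 0.31 ± 0.04 (adjusted p = 0.000467).

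**Figure D4:**
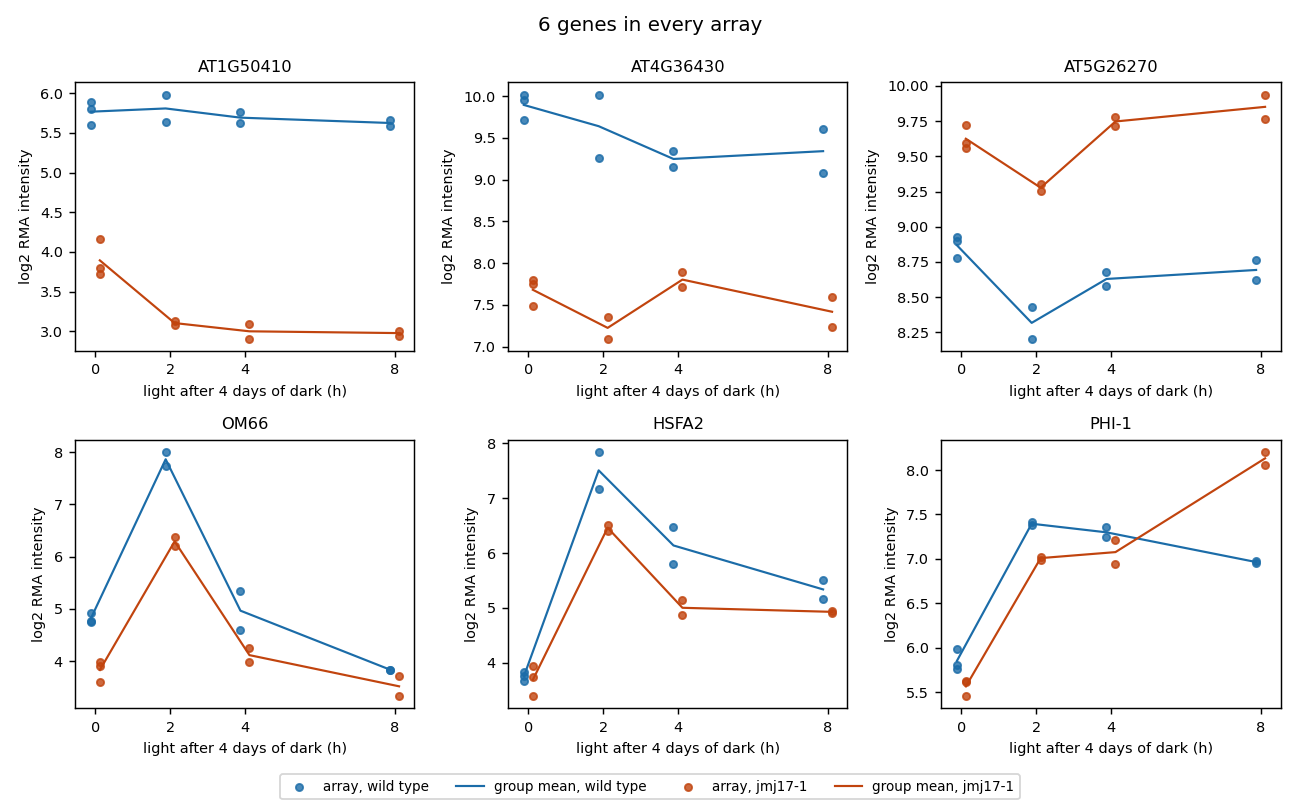
Log2 RMA intensity (vertical) of 6 genes in every array against hours of light (horizontal), with lines through group means. AT1G50410 and AT4G36430 are lower and AT5G26270 higher in jmj17-1 at each time, while PHI-1 is apart by 1.17 at 8 h.

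On the average, 8 of 11 singlet oxygen genes fell, with the same count over the list alone (median -0.46; camera adjusted p = 3.70e-07, adjusted p = 0.107 with an estimated correlation). Of 8 heat shock genes 5 fell, or 7 over the list alone (median -0.45; camera adjusted p = 2.62e-06, adjusted p = 0.333 with an estimated correlation), HSFA2 by 0.66 (adjusted p = 0.00187) and HSP22 by 0.56 ± 0.09 (adjusted p = 0.00133) among them. Starvation genes fell in 3 of 18 cases, or 6 over the list alone: MCCB by 0.21, DIN2 by 0.22 and BCAT2 by 0.27 (list median -0.05, and -0.03 without mutant dark replicate 2; camera adjusted p = 0.0289, adjusted p = 0.691 with an estimated correlation). Chlorophyll genes were higher in 15 of 16 cases with 0 past the threshold (median 0.09, and 0.04 without mutant dark replicate 2; camera adjusted p = 0.0368, adjusted p = 0.691 with an estimated correlation). Without that array both the starvation and the chlorophyll list calls on the average were lost, and PORA passed as lower (-0.30, adjusted p = 0.0104). The chlorophyll call was also lost after quantile normalization and without any 1 of 5 of the light arrays, and the starvation call without any 1 of 3. IAA29, an auxin response gene of shade growth, rose by 0.23 ± 0.07 (adjusted p = 0.0461).

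The average over the 4 times gave 203 rises and 397 falls, 600 in all (limma, adjusted p under 0.05), of a median size of 0.26, with 4 of at least 2-fold. The count was 333 without mutant replicate 2 at 4 h, 348 without wild-type replicate 2 at 8 h, 375 without wild-type replicate 1 at 4 h, 378 without mutant replicate 2 at 2 h and 381 without mutant replicate 1 at 4 h. It was 344 without the dimmest 40 percent of probe sets.

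Of the chlorophyll and light signalling genes fixed beforehand, HEMA1, CHLH, GUN4, CHL27, CAO, PORA, PORB, PORC, HY5, PIF3 and GLK2 were measured, and none passed in any comparison of the genotypes with all arrays. Without mutant dark replicate 2, PORA passed at 2 h and on the average, as given above. Of 35 list calls between genotypes, 19 up and 16 down, 0 held with an estimated correlation between genes.

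The genotypes' light responses differed in a few genes. At 2 h the interaction passed for 7 probe sets, 1 up and 6 down: ACA2, for a carbonic anhydrase, at -1.91 (adjusted p = 0.00529), and WRKY40 at -0.93 (adjusted p = 0.0411). At 4 h it passed for 7, 6 up and 1 down, with CYP81F4 at 1.87 (adjusted p = 0.0352). At 8 h 35 were up and 43 down, 78 in all (limma, adjusted p under 0.05), with PHI-1 at 1.45 (adjusted p = 0.000168) and HSP21 at 1.58 (adjusted p = 0.0249). GUN4 at -0.80 ± 0.44 (adjusted p = 0.318), PORC at -0.91 ± 0.59 (adjusted p = 0.399) and HY5 at -0.60 ± 0.20 (adjusted p = 0.115) did not pass at 8 h, and without mutant dark replicate 2 they stood at -0.30, -0.22 and -0.50. As a list, all 16 chlorophyll genes were lower in the 8 h interaction (median -0.53, and -0.13 without mutant dark replicate 2; camera adjusted p = 0.00499, adjusted p = 0.711 with an estimated correlation). Photoreceptor and light signalling genes were lower there too, with a median of -0.27 with or without that array (camera adjusted p = 0.000508, adjusted p = 0.293 with an estimated correlation). Flavonoid genes were higher in the 4 h interaction (median 0.36; camera adjusted p = 0.000245, adjusted p = 0.744 with an estimated correlation). Heat shock genes were lower in the 2 h interaction (median -0.52; camera adjusted p = 0.0237, adjusted p = 0.871 with an estimated correlation) and in that at 4 h (median -0.82; camera adjusted p = 8.44e-05, adjusted p = 0.744 with an estimated correlation). Without mutant dark replicate 2, further list genes passed singly in the interactions. At 4 h they were HSP101 (-1.14, adjusted p = 0.0375), and HSP17.6II (-1.26), WRKY33 (-0.86), WRKY40 (-0.83) and CHS (1.66), each with an adjusted p = 0.0354. At 8 h they were LUT2 (-0.63, adjusted p = 0.0372), CCA1 (-0.83, adjusted p = 0.0372) and SIG1 (-0.65, adjusted p = 0.0255).

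Falls made up 85.7 percent of the 2 h interaction calls (75.0 after quantile normalization, 50 after median centring), 14.3 percent at 4 h (6.2 and 0) and 55.1 percent at 8 h (41.2 and 31.9). The counts were 0 without mutant replicate 2 at 2 h and 44 without wild-type replicate 2 at 2 h, 0 without wild-type dark replicate 1 and 46 without mutant dark replicate 2 at 4 h, and 1 without wild-type replicate 2 at 8 h and 205 without mutant dark replicate 1 at 8 h.

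In wild type, 2 h of light raised genes of chlorophyll synthesis: CHLH, for a magnesium chelatase subunit, by 3.40 ± 0.33 (n = 2 and 3; adjusted p = 2.13e-07), GUN4, for its activator, by 3.02 ± 0.31 (adjusted p = 3.49e-07), PORC by 2.80 ± 0.42 (adjusted p = 1.83e-05) and HEMA1, for glutamyl-tRNA reductase, by 2.37 ± 0.13 (adjusted p = 4.63e-10). PORA and PORB, for protochlorophyllide oxidoreductases, fell by 2.47 ± 0.30 (adjusted p = 2.12e-06) and 1.38 ± 0.25 (adjusted p = 9.83e-05), and PORA was down by -4.65 ± 0.30 at 8 h (adjusted p = 1.55e-09). HY5, a transcription factor gene of light growth, rose by 2.26 ± 0.14 (adjusted p = 1.70e-09) at 2 h and stood at 0.82 at 8 h. The early light-induced ELIP1 rose by 5.62 ± 0.50 (adjusted p = 8.02e-08), and the shade gene ATHB2 fell by 3.72 ± 0.11 (adjusted p = 1.79e-12). At 8 h the flavonoid genes F3H and CHS had risen by 5.56 ± 0.42 (adjusted p = 8.51e-09) and 5.11 ± 0.51 (adjusted p = 2.27e-07).

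Of 16 chlorophyll genes 13 rose and 3 fell at 2 h (median 1.37; camera adjusted p = 0.00974, adjusted p = 0.501 with an estimated correlation), and the median was 2.24 at 8 h. All 26 photosystem genes rose (median 1.47; camera adjusted p = 1.73e-06, adjusted p = 0.329 with an estimated correlation), as did all 13 antenna genes (median 1.81; camera adjusted p = 0.000149, adjusted p = 0.329 with an estimated correlation). All 8 heat shock genes rose (median 3.77; camera adjusted p = 5.40e-05, adjusted p = 0.256 with an estimated correlation) and all 11 singlet oxygen genes (median 1.76; camera adjusted p = 0.000321, adjusted p = 0.248 with an estimated correlation). Of 18 starvation genes 16 fell and 1 rose (median -1.07; camera adjusted p = 6.90e-05, adjusted p = 0.256 with an estimated correlation). Dark growth and shade genes fell in 10 of 11 cases at 2 h (median -2.07; camera adjusted p = 0.000117, adjusted p = 0.0251 with an estimated correlation). This was the only list whose call held with an estimated correlation, at 2, 4 and 8 h in both genotypes. All these genes come from the deposited list, whose probe sets all changed in the mutant at 2 h. Of all its probe sets, 89.5 percent passed in wild type at 2 h.

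In wild type 2772 probe sets rose and 3354 fell at 2 h (6126), 2146 and 2749 at 4 h (4895), and 2171 and 3328 at 8 h (5499; limma, adjusted p under 0.05). The median of all probe sets moved by -0.21 at 2 h, -0.10 at 4 h and -0.20 at 8 h. With every probe set of the value table, matched by value, 8523 of 22810 passed at 2 h, 7903 at 4 h and 10362 at 8 h. The selection of the list also raises the wild-type share. At 2 h, 89.2 percent of the probe sets kept and 26.1 percent of the others had an unadjusted p under 0.05 (limma on the arrays compared).

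In jmj17-1, the same genes of chlorophyll synthesis changed with light. CHLH was higher than in the dark by 2.26 at 4 h and 2.98 at 8 h. At 2, 4 and 8 h GUN4 was higher by 2.53, 1.98 and 2.16, and PORC by 2.43, 2.65 and 2.68. PORA fell by 3.33, 4.32 and 5.35, and ELIP1 rose by 5.75 at 2 h. These changes start from a dark mean that includes mutant replicate 2, and without it GUN4 was higher by 3.03, 2.48 and 2.65, PORC by 3.12, 3.33 and 3.37, CHLH by 2.80 and 3.52 at 4 and 8 h, and ELIP1 by 6.52 at 2 h, while PORA stood at -2.86, -3.86 and -4.89. HY5 rose by 1.82 at 2 h and stood at 0.22 at 8 h (adjusted p = 0.169), or 1.92 and 0.31 without that array. At 2 h, 6831 of 6847 probe sets passed in the mutant because of how the list was selected. That all genes of a list changed there was thus fixed, though not their direction. The photosystem genes all rose at 2 h (median 1.28, and 1.49 without mutant dark replicate 2; camera adjusted p = 1.30e-06, adjusted p = 0.31 with an estimated correlation), as did the 8 heat shock genes (median 3.15, and 3.10 without that array; camera adjusted p = 7.58e-05, adjusted p = 0.255 with an estimated correlation).

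In the mutant 2924 probe sets rose and 3907 fell at 2 h (6831), 2187 and 3037 at 4 h (5224), and 2130 and 3269 at 8 h (5399; limma, adjusted p under 0.05). The deposited table holds only probe sets with an unadjusted p of at most 0.0237 in the mutant at 2 h against its dark group, so that count is set by the selection. The median of all probe sets moved by -0.34 at 2 h, -0.14 at 4 h and -0.19 at 8 h.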

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

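The tests of a single mutant dark array, of genotype as the source of the stress list differences, of linkage to JMJ17 and of the splits of the arrays in the dark and on the average were chosen only after the result was seen.

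Photosynthesis lists were higher in the mutant dark group. This is consistent with the effect of a single array: without mutant dark replicate 2 the median of the 16 chlorophyll genes was 0.008 instead of 0.358. A response to light as in the wild type at 2 h is excluded, since the photosystem genes of this array deviated by a fraction of 0.51 of that response while its dark growth and shade genes, which fall in light, deviated by -0.056 of it (mean deviation 0.101 ± 0.059), and PORA, which also falls, stood at 11.03 against 9.57 and 9.71 in the other mutant dark arrays. Other values lean towards light: starvation genes, which fall in light, were at a fraction of 0.113 with 1 of 18 higher, early light-induced genes at 0.371 and flavonoid genes at 0.421, and the array's correlation with the wild-type light change, 0.245 at 2 h and 0.395 at 8 h, was the highest of the dark arrays. Light of another kind or length was not tested.

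Heat shock and singlet oxygen lists were lower in the mutant at 2 and 4 h. Whether the mutant was further along the wild-type time course is not settled for these lists. The slope of the genotype difference on the wild-type change to the next time was at most 0.179 across all probe sets. The heat shock list needed 0.341 to 2.615 and the singlet oxygen list 0.296 to 3.926. An advance by the same fraction for all genes thus falls short as the whole cause. The test cannot exclude an advance in which these genes change faster than others, and each slope rests on single wild-type arrays. The correlation of the genotype difference with the wild-type change was positive in each case (0.19 to 0.363). Flavonoid genes moved the same way at 4 h (ratios 0.263 and 0.504), while their ratios at 2 h were -0.692 and 0.371. An advance along the time course, as a part or as the whole, stays open. A single array of the 2 in a group is excluded only as the whole cause of the list shift. The heat shock median was -0.404 or lower, and its 8 genes lower, with any of 8 arrays left out. At 2 h the median went from -0.754 to -0.404 without wild-type replicate 1, so part of its size rested on that array. The single-gene calls were not stable to leaving out an array, as given above. Genotype cannot be told apart from a shared difference in harvest, as each genotype has 2 arrays per light time and the labels give no harvest.

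Genes apart at all 4 times were AT1G50410, AT4G36430 and AT5G26270. A variant linked to the JMJ17 locus and lying in the gene itself is excluded for AT4G36430 and AT5G26270, of which 0 lie on chromosome 1. A linked variant that changes them from elsewhere was not tested, and neither was a variant at another place in the mutant line. For AT1G50410, on chromosome 1 at a distance of 1223 protein-coding genes from JMJ17, linkage cannot be told apart from an effect of the mutation because no parent line was measured, although it lies outside the 1000 genes on each side of JMJ17 in which calls on the average were not more frequent (6.5 percent against 6.9 percent of other probe sets, Fisher p = 0.795). A sequence variant under a single probe set also cannot be told apart, since 0 of the genes have a further 1-gene probe set among those tested.

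Regrouping the 6 dark arrays gave 10 splits, of which 1, the real one, called as many as 123 probe sets and the next called 2; the splits are too few for a share under 0.05. For the average over times, 1 of 100 splits, the real one, called 600 and the highest other 431, in a split that moved only 2 arrays from the real one; the next called 62.

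The interaction of genotype and light was listed because it tests a difference between the groups' responses. It passed for 7 probe sets at 2 h, 7 at 4 h and 78 at 8 h. At 2 h the values were 0.64 for IRT3, -1.91 for ACA2, -0.99 for AT1G35210, -0.93 for WRKY40 and -0.65 for AT1G33590. At 4 h they were 2.72 for AT4G11190, 1.87 for CYP81F4, 1.72 for AT4G17470, 1.62 for IGMT5, 1.47 for AT2G18210, 1.09 for AT5G10770 and -0.66 for AT1G12070. At 8 h the largest were 1.93 for AT2G41730, 1.58 for HSP21, ECS1 and MDHAR alike, 1.45 for PHI-1, 1.37 for GSTU12, -1.57 for AT2G47780, -1.19 for EXPA10, -1.08 for ESE3, -1.05 for AT5G66260, -1.04 for AT2G39920 and -0.96 for AT5G59480. A group mean used was among the dimmest 5 percent of probe sets for ACA2, AT1G35210 and HSP21, so the exact sizes of these are not established.

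Probe sets outside the deposited table, read from the value table with columns matched by value, also passed between genotypes: 47 in the dark, 117 at 2 h, 43 at 4 h, 38 at 8 h and 245 on the average. In that same fit only part of the main calls passed again. These were 57 of 123 in the dark, 203 of 361 at 2 h, 97 of 186 at 4 h, 54 of 87 at 8 h and 383 of 600 on the average.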

How the results depend on the processing

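With 2 arrays per light group and a deposited list of 6847 probe sets, counts depended on single arrays. Without the dimmest 40 percent of probe sets fewer passed, and how far dim values, down to an intensity of 3.22, stand above background was not tested. Of 5575 values of 334 gene results under the alternatives, 5113 stayed on their side of the threshold, 452 became weaker (293 with an array left out), 10 stronger and 0 reversed. These results include always-named genes that did not pass and the largest light responses, so the share that stayed does not describe the genotype calls. The cause of the changes under the alternatives was not tested, except that adjustment over 22810 probe sets and an added fold threshold lower counts by construction.

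Without the dimmest 40 percent of probe sets, counts were 41 in the dark, 186 at 2 h, 86 at 4 h and 344 on the average; for light 3863, 3192 and 3472 in wild type and 4109, 3295 and 3348 in the mutant at 2, 4 and 8 h; and 4 and 32 for the 4 and 8 h interactions. With array weights they were 79 in the dark, 322 at 4 h, 226 at 8 h, and 19, 33 and 195 for the interactions. Adjusted over 22810 probe sets they were 29, 142, 51 and 22 at the 4 times, 266 on the average and 1, 0 and 4 for the interactions. With only the arrays compared they were 13 in the dark, 227 at 2 h, 120 at 4 h and 1 for both the 2 h and the 8 h interaction. With a fold of at least 1.5 they were 51 in the dark, 160 at 2 h, 46 at 8 h, 35 on the average, 3531, 2505 and 3440 for wild-type light and 3614, 2801 and 3324 for mutant light.

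With the full value table, 8523, 7903 and 10362 passed in wild type and 8091, 8251 and 10349 in the mutant at 2, 4 and 8 h, and 2, 14 and 35 for the interactions. Quantile normalization gave 4 and 16 for the 2 and 4 h interactions, median centring 2, 12 and 138 for the 3, adding 16 before the log 41 and 15 for the 2 and 4 h ones, and trend with robust settings 4 at 4 h.

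With each array left out in turn, counts ran from 24 to 445 in the dark, 88 to 367 at 2 h, 11 to 114 at 4 h, 7 to 80 at 8 h and 333 to 738 on the average. For light they ran from 5591 to 5973, 4325 to 4689 and 5036 to 5358 in wild type, and 6515 to 6793, 4531 to 5130 and 4903 to 5371 in the mutant. For the interactions they ran from 0 to 44, 0 to 46 and 1 to 205.

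List calls between genotypes, 35 in all, were 0 with an estimated correlation, 27 after quantile normalization, 36 with all probe sets of a gene, 44 against the full table and 27 to 39 with an array left out. For light and the interactions, list calls were not run with arrays left out.

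With the replicate number as a block, counts were 141 in the dark, 348 at 2 h, 185 at 4 h, 69 at 8 h and 576 on the average, and 35 list calls. Whether the numbers pair is not settled. Residuals of arrays of the same number correlated at -0.034, -0.025 and 0.145 in the dark, 0.092 at 2 h, 0.036 at 4 h and 0.215 at 8 h. In the dark 2 of 6 arrays correlated best with their own number, namely replicate 3 of wild type and replicate 3 of the mutant.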

Other observations

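Enrichment of gene ontology terms among the genes that differed was tested after seeing the data, against the 6481 genes of 1-locus probe sets. Of 273 genes lower in jmj17-1 at 2 h, 56 belonged to the response to chitin, against 8.1 expected by their share (adjusted p = 2.04e-30), 21 to ethylene biosynthesis (2.1 expected; adjusted p = 1.65e-14) and 29 to the response to hydrogen peroxide (4.5 expected; adjusted p = 2.86e-14). At 4 h, 23 of 119 lower genes belonged to the response to heat (2.4 expected; adjusted p = 2.54e-14) and 13 to endoplasmic reticulum stress (1.5 expected; adjusted p = 1.74e-07). Of 197 genes higher on the average, 14 belonged to sterol biosynthesis (2.9 expected; adjusted p = 0.000613) and 11 to brassinosteroid biosynthesis (2.4 expected; adjusted p = 0.00564). Of terms tested, 7 passed for falls in the dark, 45 at 2 h, 32 at 4 h and 53 on the average, and 0 at 8 h. These tests take genes as independent, and genes of a term move together, so their p-values are too small.

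Further lists differed between genotypes in the dark, at the preset correlation only. Measured were 6 of 19 plastid, 5 of 21 histone methylation and 11 of 12 shade loci. For heat shock they were 8 of 8, for abscisic acid 14 of 30 and for fatty acid breakdown 9 of 15. All come from the deposited list, whose probe sets all changed in the mutant at 2 h, so a call does not describe the loci left out. Higher were plastid gene expression and import (median 0.18, and 0.10 without mutant dark replicate 2; camera adjusted p = 0.0311; adjusted p = 0.638 with an estimated correlation), histone lysine methylation (median 0.21, and 0.19 without that array; camera adjusted p = 0.0311; adjusted p = 0.592 with an estimated correlation) and dark growth and shade (median 0.17, and 0.12 without it; camera adjusted p = 0.0405; adjusted p = 0.398 with an estimated correlation). Lower were heat shock (median -0.21, and -0.18 without it), abscisic acid and dehydration (median -0.18, and 0.04 without it) and fatty acid breakdown (median -0.10, and -0.02 without it), each with a camera adjusted p of 0.0311 and adjusted p = 0.638 or 0.639 with an estimated correlation. All 6 calls were lost without that array, but each was lost without another dark array too. For shade these were wild-type replicates 1 and 3 and mutant replicates 1 and 3. For histone methylation they were wild-type replicates 2 and 3 and mutant replicates 1 and 3. Without wild-type replicate 2 the plastid, abscisic acid and fatty acid calls were lost, and without wild-type replicate 1 the heat shock call. The plastid call was also lost without mutant replicate 1, and the fatty acid call without mutant replicate 3.

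In the dark, early light-induced proteins (5 measured, median 0.27, camera adjusted p = 0.279), heme and tetrapyrrole control (3 measured, median 0.12, camera adjusted p = 0.929), dividing cells (3 measured, median -0.15, camera adjusted p = 0.127), root (3 measured, median 0.01, camera adjusted p = 0.929), flavonoids (median 0.08, camera adjusted p = 0.929) and starvation (median -0.04, camera adjusted p = 0.315) did not differ past the threshold. Without mutant dark replicate 2 their medians were 0.028, -0.082, -0.117, -0.017, -0.098 and 0.025 in that order. The circadian clock list did not differ past the threshold either (camera adjusted p = 0.953), with a median of 0.10 and a mean of 0.03 while the test leaned down. In the 2 h interaction the photosystem list had a median of -0.13 while the test leaned up, without passing. Its median there was 0.15 without mutant dark replicate 2. Of the seed storage list only OLEO2 was measured.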
